A study of Mus musculus with 6 samples.

How the data were processed

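Genomic DNA of 6 T-cell acute lymphoblastic leukaemia (T-ALL) clones from mice was compared with reference DNA from spleen on 2-colour oligonucleotide arrays for comparative genomic hybridisation. Each clone was hybridised once. Per the labels, the clone was labelled with Cy3 and the reference with Cy5 on all 6 arrays, so no dye swap was present and a dye effect could not be averaged out. The clones were grouped by the organ the labels name, thymus for #003, #007, #483 and #958 and spleen for #1003 and #1065. The labels give no strain, sex or relation of the mice and do not say whether 1 reference DNA served all arrays.

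Per the file headers, the authors deposited the output of Agilent Feature Extraction, version 10.7.3.1 for #003 and #007 and version 10.10.1.1 for the other 4 clones, with probe coordinates of the mouse build mm9. Per the file headers, the processed signals are intensity values with the background subtracted and a linear dye normalisation applied, without loess. The deposited log ratios are log10 of red over green, and the series value table held the same log10 values at every feature (largest difference 0). The column medians of that table lay between 6e-05 and 0.00528. It was turned to clone over reference before use, and its scale and direction were settled by this match. The file headers place the arrays on 3 slides, slide 1 with #003 and #007, slide 2 with #483, #1003 and #1065, and slide 3 with #958.

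Each array held 180880 spots, of which 174305 were not controls. They stood for 170305 distinct probes, 161460 of them on autosomes at a median spacing of 10843 bp. The log2 ratio of clone over reference was computed from the processed signals, spots with outlier flags (101 to 140 per array) were left out, spots of 1 probe were averaged, and each array was centred on the median of its autosomal probes. The median raw signal was 223 to 378 in the clone channel and 333 to 532.5 in the reference channel, over local backgrounds of 20 to 43 and 54 to 59. Between 55 and 184 spots per array were not well above background in at least 1 channel. Smoothed profiles of the arrays shared a wave of low amplitude, with correlations across probes (which are not independent) of 0.637 to 0.94 between arrays. The spread of differences between neighbouring probes, a measure of noise, was 0.11 for #003, 0.18 for #007, 0.16 for #483, 0.13 for #958, 0.15 for #1003 and 0.16 for #1065 on the log2 scale. With 1 array per clone, the number of arrays limits the precision, and p-values across clones measure the spread between clones, technical error included.

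Log2 ratios were segmented per chromosome by exact penalised least squares with a penalty of 3 times the noise variance times the natural log of the number of probes. A segment was called a gain or a loss at a mean of at least 0.25 in either direction with at least 5 probes, and neighbouring called segments of one sign were joined. An autosome was called as changed over its whole length when at least 80% of its probes lay in called segments of 1 sign. The percent of altered sequence was taken over 2407.8 Mb of autosomal sequence, each probe standing for the stretch up to the midpoints with its neighbours. Sharing between clones was tested by rotating each clone's calls along the joined autosomes in 10000 draws (one-sided). Thymus and spleen clones were compared by an exact permutation test over 15 splits (two-sided), by Fisher's exact test for counts of clones, and by limma on the mean log2 ratio in 100 kb bins with at least 3 probes and Benjamini-Hochberg adjustment. The same bins were tested against 0 over all 6 clones with limma, which leaves out the spread of the reference. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.

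The array files name no genes, and the gene table in use belongs to another build (GRCm38.p6), so no gene was placed by coordinate. The tests of gene lists and of antigen receptor loci by position that were fixed before the data were examined were therefore not run. In their place, 8 gene lists fixed beforehand were tested at the level of whole chromosomes. The statistic was the number of pairs of gene and clone on a gained autosome, set against 10000 permutations of the autosome labels (one-sided). Of 225 list entries 222 were matched by symbol, 1 was not matched and 2 repeated another entry under a second name. The rule for named genes listed genes to be given always, members of the lists inside called segments under 10 Mb, and for each clone the 5 called autosomal segments under 10 Mb with the largest absolute mean, and likewise regions shared by at least 3 clones. The genes are given by chromosome, their places in segments could not be read, and the segments are given by position. Some of the items under this rule are not reported here. Regions followed across all clones were chosen after their values were seen. Each takes its ends from 1 clone, either from called segments joined before the minimum of probes was applied or, for the short loss on chromosome 13, from runs of at least 2 probes at or below -1.5. Flanking values are medians over the 100 probes on each side.

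On simulated arrays with the noise of each clone, all 24 planted segments of 5 probes at a log2 level of 1 were found, 7 of 24 at 0.5 and 0 of 24 at 0.3. With 50 probes all 24 were found at 0.3. Outside the planted segments 55 of 2024580 probes were called. The permutation by rotation passed p = 0.05 in 4 of 100 simulations without sharing and in 100 of 100 with a region shared by 4 clones. The simulated segments were shorter than any chromosome gained in the data, so these rates do not carry over to gains of whole chromosomes. The list test passed in 2 of 100 with genes spread evenly and in 89 of 100 with a list gathered on the chromosome gained most. That list was gathered more strongly than any of the lists tested, so its rate does not carry over to them. Of 200 bins shifted by 0.3 among 20936, limma found 173 against 0 and 75 between the organs, and at 0.6 it found 196 and 160. These simulations carried no wave of the kind described with the results. The alternatives tried were normexp background correction on the median signals (offset 50; the files held no mean signals), centring on the mode, keeping flagged spots, leaving out dim probes, call thresholds of 0.15 and 0.40, penalty multiples of 2 and 5, minimums of 3 and 10 probes, the series value table, 1 Mb bins, no minimum per bin, the slide as a block, the slide with both organs alone, and each clone left out. Joining segments before the minimum of probes and removing the smoothed profile shared by the other clones (over 51 probes, or a longer profile over 401) were added after seeing the data. The profile over 51 probes also held short regions shared by several clones and turned some of their means around, so under it only the region means that changed sign are given, and the longer profile was added. A correction for GC content was not run, for want of a genome of the same build.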

Results

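The series compared DNA of 6 T-ALL clones with reference spleen DNA by array comparative genomic hybridisation. The leukaemias had arisen in mice that received haematopoietic stem and progenitor cells (the LSK fraction) carrying a transduced gene, and the study's title places them in work on mTORC1, mTORC2 and translation driven by eIF4E. A log2 ratio of 0 stands for equal amounts of clone and reference DNA, and 3 copies against 2 would give 0.58. Of the clones, 4 came from thymus (#003, #007, #483, #958) and 2 from spleen (#1003, #1065). Each was measured on 1 array of 170305 probes, so values of single clones have no replicate, and SDs given for a single clone are across probes or bins.

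Which chromosomes were gained or lost as a whole was the first question. All 4 thymus clones carried at least 1 gained autosome, and neither spleen clone did. Chromosome 15 was gained in #007 (median log2 ratio 0.46 ± 0.17, SD across bins of 1 Mb), #483 (0.47 ± 0.06) and #958 (0.52 ± 0.10). Chromosome 14 was gained in #003 (0.49 ± 0.13) and #958 (0.51 ± 0.26), and #007 also gained chromosomes 1 (0.44 ± 0.16) and 4 (0.46 ± 0.17). No autosome was lost as a whole.

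The 7 gains lay at 0.44 to 0.52 on the log2 scale, below the 0.58 of 3 copies over 2. Medians of the other autosomes lay between -0.11 and 0.06 across the 6 clones. Gains of whole chromosomes in 4 of 4 thymus clones against 0 of 2 spleen clones gave p = 0.0667 in Fisher's exact test (two-sided), the smallest p that 4 against 2 allows. The chromosome 15 gain alone, in 3 of 4 against 0 of 2, gave p = 0.4 in the same exact test. At a call threshold of 0.40 only 2 of the 7 gains still met the rule for whole chromosomes, chromosome 15 in #483 and #958. With normexp background correction 6 did, all but chromosome 1 in #007.

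**Figure D1:**
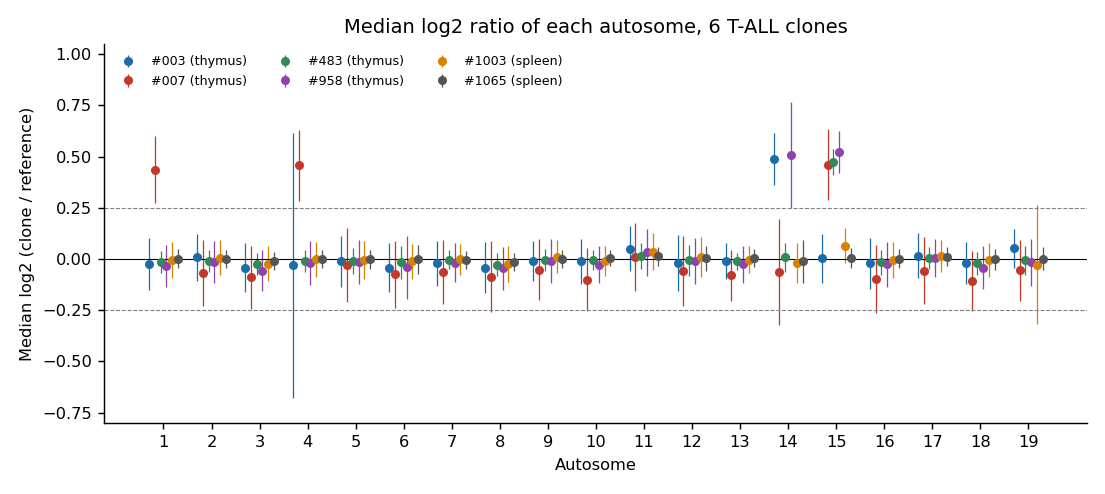
Median log2 ratio of clone over reference for each of the 19 autosomes (points, with bars of 1 SD across 1 Mb bins) in 6 clones, with dashed lines at the call threshold of 0.25 in both directions. The 7 gained chromosomes stand at 0.44 to 0.52 and the others between -0.11 and 0.06. The long bar of #003 on chromosome 4 comes from a deep loss on that chromosome.

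The amount of altered sequence differed widely between clones. Called segments covered 35.7% of autosomal sequence in #007, 9.14% in #958, 7.41% in #003 and 4.33% in #483, but 0.468% in #1003 and 0.174% in #1065. The number of called segments was 135 in #007, 28 in #003, 18 in #958, 9 in #483 and 12 in each spleen clone. These are not counts of separate alterations. The minimum of 5 probes was applied before joining, so deep losses were split or left out in part. The chromosome 4 loss of #003 (165 probes) was called only in pieces of 5 to 9 probes. In #958, 12 of the 53 probes of a chromosome 14 loss were called. The percent lost leaves out the parts not called. In #483 and #958 nearly all of the altered sequence was gain (4.28% and 9.04%), while #007 had 14.4% gained and 21.3% lost. Of the 109 losses in #007, 102 had means above -0.40, with a median over all losses of -0.32. After removal of a wave shared by all arrays (over 51 probes), lost sequence was 0.263% in #007, and in #003 it was 0.312% where it had been 2.48%. With a longer profile removed instead, it was 4.46% in #007 and 0.192% in #003.

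The mean was 14.2% ± 14.5 (SD, n = 4) in thymus clones and 0.321% ± 0.208 (SD, n = 2) in spleen clones, a difference of 13.8 percentage points that gave p = 0.267 in the exact permutation test, where 15 splits allow no p under 0.0667. Within the slide that held both organs, #483 exceeded the mean of the spleen clones by 4.01 points. The value of #007 was 10.5% at a threshold of 0.40 and 18.8% with the shared wave removed over 51 probes. Leaving out #007, the difference was 6.64 points (exact permutation p = 0.1).

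**Figure D2:**
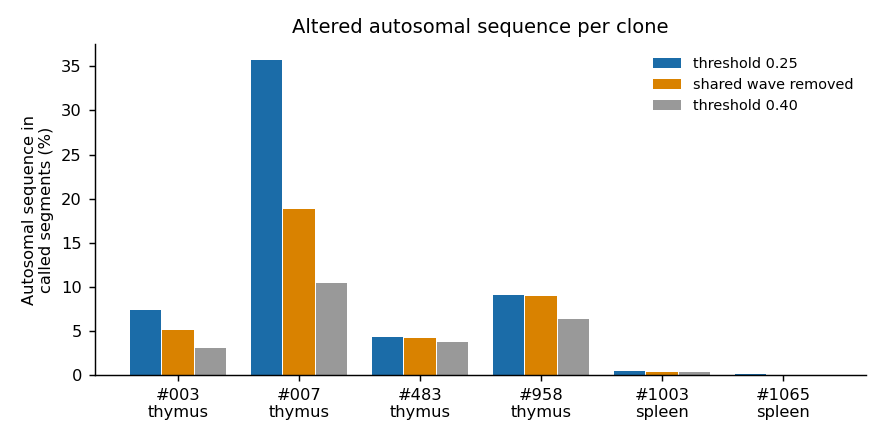
Percent of autosomal sequence in called segments for each clone at the main threshold of 0.25, after removal of the wave shared by the arrays, and at a threshold of 0.40. #007 changes from 35.7% to 18.8% and 10.5%, and #1003 and #1065 stay below 0.5% in all 3.

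The longest deep loss was found in #003 alone. This clone had lost chromosome 4 from 88843162 to 93562777 (4.72 Mb, 165 probes) with a mean log2 ratio of -3.94 ± 1.02 (SD across probes), where the other 5 clones had means between -0.18 and 0.22. Of these 165 probes, 87 were well above background in both channels, so the level in #003 is partly a bound set by background. #1003 had also lost part of chromosome 19, from 27880250 to 37001415 (9.12 Mb, 694 probes, mean -0.75 ± 0.41).

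Among the remaining segments under 10 Mb that led each clone by absolute mean were losses on chromosome 9 in #007 (32298734 to 32506379, -0.73), on chromosome 1 in #1065 (43412444 to 43507569, -0.63) and on chromosome 5 in #483 and #958 (136887115 to 137089632 in both, -0.68 and -0.82). All 5 leading segments of #003 lay inside its chromosome 4 loss. Cdkn2a, a tumour suppressor locus of the cell cycle, lies on chromosome 4. Its place relative to the loss of #003 was not analysed here, for want of gene positions in mm9. With normexp background correction the chromosome 4 loss of #003 was shallower, at -1.346.

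**Figure D3:**
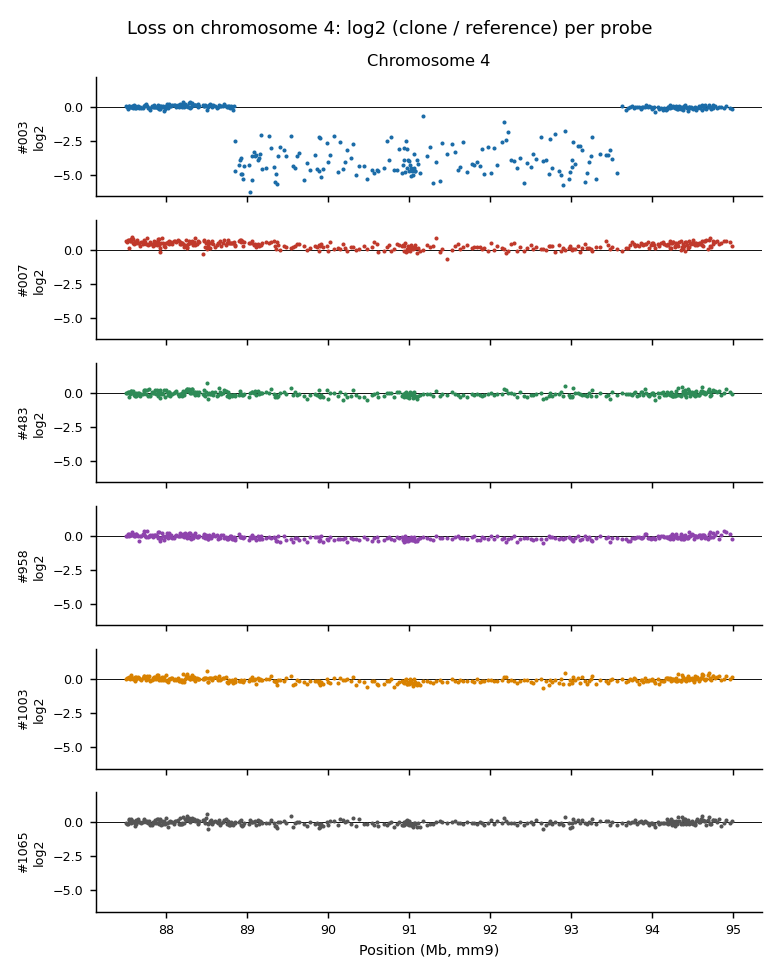
Log2 ratio of each probe (points) against position in mm9 on chromosome 4, 1 row per clone. The loss of #003 averages -3.94, and the other 5 clones have means between -0.18 and 0.22 over the same probes.

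Short losses on chromosomes 6 and 14 were found in every clone except #003. On chromosome 14 the loss ended at 54741487 in #007, #483, #1003 and #1065 and at 54779814 in #958, whereas its first probe lay anywhere from 54181273 to 54635729. In #1065 it came in 2 pieces, of which the right one had the same first and last probe as the loss of #1003 (54635729 to 54741487). Over the extent it had in #007 (54278607 to 54741487, 46 probes), means were -3.74 ± 1.56 (SD across probes) in #007, -3.40 ± 1.90 in #958, -1.58 ± 1.06 in #1065, -0.87 ± 1.18 in #1003 and -0.81 ± 1.01 in #483, against 0.84 ± 0.18 in #003, whose flanking probes stood at 0.61. Of the 46 probes, 19 in #007 and 20 in #958 were well above background in both channels, so these depths are bounds, and with normexp the means were -0.998 in #007 and -0.91 in #958. On chromosome 6, between 41018389 and 41501220 (43 probes), means were -2.83 ± 1.70 in #958, -1.44 ± 1.16 in #483, -1.40 ± 1.36 in #1065 and -0.77 ± 0.57 in #007. Of these 43 probes, 25 in #958, 28 in #1065 and 32 in #483 were well above background in both channels, and with normexp the mean of #958 was -0.90. Over the same probes #1003 stood at 0.07 ± 0.38 and #003 at 0.22 ± 0.12, with the flanking probes of #003 at -0.07. #1003 had only a smaller loss from 41226805 to 41337467 (-0.44), beside a called gain from 40976427 to 41214302 (24 probes, 0.36).

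A pair of probes on chromosome 13 (19286254 to 19298226) had means of -4.40 in #007 and -4.91 in #958, with both probes below -1.5, and 0.32 in #003. The flanking probes of #003 stood at 0.007 there. #003 was thus above its flanking probes at the losses of the other clones on chromosomes 6, 13 and 14, and the cause was not tested. In #483, #1003 and #1065 the means of -2.35 to -2.21 rested on a single probe (-4.09 to -3.79), the other being at -0.79 to -0.61. In each of these 5 clones at most 1 probe of the pair was well above background in both channels, and with normexp the means were -0.71 in #007 and -1.27 in #958. This pair is under the minimum of 5 probes and was picked after its values were seen. On chromosome 12, #003 alone had lost 114670169 to 114805372 (12 probes, -2.55 ± 1.03, and -0.99 with normexp), where the other clones were at 0.61 to 0.80. The antigen receptor loci Tcra, Tcrb and Tcrg, whose gene segments are joined in developing T cells, lie on chromosomes 14, 6 and 13, and Igh, the immunoglobulin heavy chain locus, on chromosome 12. Whether the losses fall in these loci was not analysed here, for want of gene positions in mm9.

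**Figure D4:**
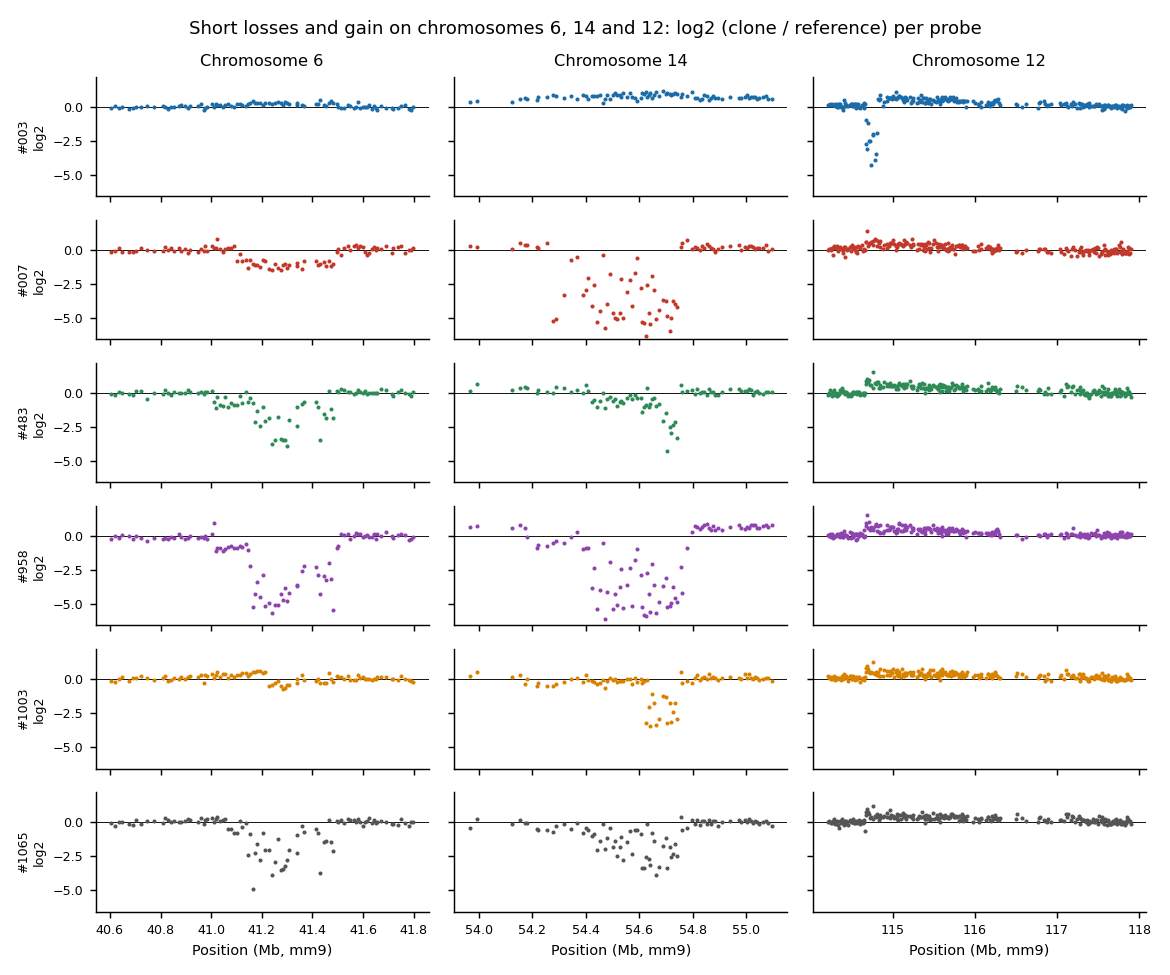
Log2 ratio of each probe (points) against position in mm9 on chromosomes 6, 14 and 12, 1 row per clone. Losses on chromosomes 6 and 14 are present in 5 clones (smaller on chromosome 6 in #1003) and absent in #003, which instead has a loss averaging -2.55 at the start of the chromosome 12 gain.

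Sequence altered in the same direction in at least 3 clones came to 80.6 Mb. Gains made up 79.9 Mb, mainly chromosome 15 in #007, #483 and #958. Losses made up 0.718 Mb, or 1.17 Mb with segments joined before the minimum of probes. The spleen clone #1065 also had short called gains on chromosome 15, from 34597761 to 34866764 (20 probes, 0.51) and from 38621102 to 38732114 (6 probes, 0.55). A gain on chromosome 12 from 114670169 to 117105437 (142 probes) was shared in part by all 6 clones. From 114817826 to 117105437 (130 probes), which leaves out the loss of #003, clone means ran from 0.23 in #007 to 0.46 in #003. The gain started at 114670169 in all clones but #003, whose chromosome 12 loss began at that probe. The far end of the gain differed in all 6, from 115252236 in #007 to 117318285 in #483. A loss on chromosome 14 from 69876584 to 70090608 (23 probes) had the same ends in the 4 thymus clones and was not called in the spleen clones. Its means were -0.32 in #003, -0.88 in #007, -0.87 in #483 and -0.34 in #958, against 0.09 in #1003 and 0.07 in #1065. A loss on chromosome 11 (3030764 to 3091840, 7 probes) was called in #003 (-0.43), #007 (-0.38) and #1003 (-0.32), but the other clones were also below 0 there, at -0.29 in #483, -0.24 in #958 and -0.19 in #1065.

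Rotation of the calls gave as much shared sequence with p = 0.0053, and sharing by 6 clones at 1 probe with p = 2e-04 (permutation by rotation, 10000 draws). Rotation does not keep chromosome boundaries, so gains of a whole chromosome rarely line up in the draws. The p for shared length rests mainly on chromosome 15. It therefore does not test whether clones gain the same chromosome more often than at random. The most clones sharing a probe came to 5 at a threshold of 0.40 and with the wave removed over 51 probes or over the longer profile (permutation by rotation, p = 1e-04, 3e-04 and 4e-04). The sharing by 6 clones lay in the chromosome 12 gain, but at 0.40 the 5 clones shared the chromosome 6 loss. At most 4 clones then shared a probe of the chromosome 12 gain. That gain was called in 2 clones with the wave removed over 51 probes and in 5 with the longer profile removed. The shared length rested on the clones with the chromosome 15 gain, since it came to 3.22 Mb without #007 (p = 0.0085, permutation by rotation), 2.51 Mb without #483 (p = 0.0443, permutation by rotation) and 3.41 Mb without #958 (p = 0.0242, permutation by rotation). At a threshold of 0.15 it came to 333 Mb.

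Across the 6 clones, 2474 of 20936 bins of 100 kb had higher and 3209 lower log2 ratios than 0 (limma, adjusted p under 0.05). The shifts were mostly small, with a median absolute mean of 0.14, and 354 bins had means of at least 0.25 and 103 of at most -0.25. Chromosome 15 held 307 of the higher bins and none of the lower. The deepest bin was on chromosome 14 (54700001 to 54800000), with a mean of -1.66 and an adjusted p of 0.0498 in limma, lower in 5 of 6 clones. These counts depended on the wave that all arrays shared. With it removed over 51 probes, which can also remove part of the sequence altered in several clones, limma called 0 bins (3162 at an unadjusted p under 0.05). Single clones decided the counts too, which were 1 higher and 0 lower without #1003 (7558 at an unadjusted p under 0.05 in limma), 371 and 679 without #958, 1111 and 1941 without #483, and 1472 and 1902 without #003. With the slide as a random block they were 1505 and 2358.

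Between the organs limma called 0 bins, with 608 at an unadjusted p under 0.05, and also 0 with the slide as a block (154 unadjusted). Within the slide that held both organs, 1 thymus clone against 2 spleen clones, 886 bins were higher and 19 lower in the thymus clone, and 869 of the higher bins lay on chromosome 15, which #483 had gained. Without #003, the thymus clone with no gain of chromosome 15, 545 bins were higher in thymus clones, all on chromosome 15, and without #1065 limma called 2 bins, both on chromosome 19. In the last fit and in the single slide, the lone clone of 1 organ was assumed to vary like the clones of the other.

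The genes named beforehand were described by the state of their chromosome. Myc, a transcription factor that drives growth, Il7r, the interleukin 7 receptor chain, and Rictor, a subunit of mTORC2, lie on chromosome 15, gained in 3 clones. Rb1, the retinoblastoma tumour suppressor, lies on chromosome 14, gained in 2 clones. Mtor, the kinase of both mTOR complexes, and Cdkn2a lie on chromosome 4, gained in 1 clone. Chromosome 4 also carried the deep loss of #003 (-3.94), and the places of these genes relative to that loss were not analysed. Notch1 (chromosome 2), Fbxw7 and Eif4e (3), Trp53 and Ikzf1 (11) and Bcl11b (12) lie on chromosomes that no clone gained as a whole.

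None of the 8 lists passed an adjusted p of 0.05 against permuted chromosome labels. Of 38 genes of PI3K, mTOR and translation initiation, 9 lay on a chromosome gained in some clone, making 13 gains of gene and clone out of 228 (14.02 under permutation, adjusted permutation p = 0.962). The counts were 4 of 21 Notch and Myc genes, 5 of 21 genes of the cell cycle and p53, 5 of 34 T lineage transcription factors, 5 of 36 genes of receptor, RAS and JAK-STAT signalling, 6 of 20 apoptosis genes and 4 of 21 genes in a list of chromatin regulators that also held ribosomal protein genes (Rpl22 among the 4; autosomal members throughout), each with an adjusted permutation p of 0.962 or 0.966. The comparison list of genes outside the blood system had the lowest value, with 17 gains of 144 against 8.86 under permutation (adjusted permutation p = 0.456, raw p = 0.057), and 8 of its 24 autosomal genes lay on a gained chromosome. The test reads whole chromosomes only and carries no information on focal changes.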

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

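All tests weighed in this part were chosen after the results were seen. Of 20 quantities compared among the 4 thymus clones, 7 had 1 clone far from the other 3. Chance gives about 1 in 20 groups, but most of these quantities were picked because they stood out, so that rate is no comparison here. With the main settings, #007 stood apart by its altered sequence (35.7%), its number of called segments (135) and its gains of chromosome 1 (0.44) and chromosome 4 (0.46). The segment count depended on the shared wave. With that wave removed over 51 probes, #007 had 14 segments, against 22 in #003, 16 in #958 and 10 in #483. With the longer profile removed, #007 had 68. Altered sequence of #007 with the wave removed over 51 probes was 18.8%, still the highest, with #958 next at 9.01%. #003 stood apart by the absence of a chromosome 15 gain (median 0.003), its chromosome 4 loss (-3.94) and its chromosome 12 loss (-2.55). The mean over the distal chromosome 14 loss was below 0 in every thymus clone and above 0 in both spleen clones, a difference of -0.68 that was not tested. On chromosome X, left out of the comparisons, #1003 had a gain from 73480787 to 80564120 (338 probes) with a mean of 0.72, where the other clones had means of -0.29 to 0.13.

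The losses on chromosomes 6 and 14 were present in 5 clones (smaller on chromosome 6 in #1003) and not in #003. An effect of slide 1 was argued against by #007 on the same slide, which lay below #003 by a difference of -4.58 over the chromosome 14 loss. The size of that difference is partly set by background and by the gained chromosome 14 of #003. It also follows in part from the choice of the region, which was taken from #007. With normexp the means were -0.998 in #007 and 1.06 in #003. An exchange of clone and reference DNA was argued against by the distal chromosome 14 loss, which relative to flanking probes was below 0 in #003 (-0.86) as in the other thymus clones (-0.93 to -0.87). For joining of gene segments at an antigen receptor locus, 1 shared end and 1 varied end were looked for. On chromosome 14, 4 of the 5 clones shared the right end of the loss and 2 shared a left end. On chromosome 6 no end was shared by more than 2. Both ends can differ between clones when different gene segments are joined, so these counts cannot decide for or against joining. Joining therefore stays open, the loci were not placed in mm9, and whether #003 is of another cell type or stage, or carries a wrong label, was not tested.

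The chromosome 12 gain was called in 6 of 6 clones with the main settings. The wave shared by the arrays stays open, since with the longer profile removed the mean over the gain was 0.01 in #007 and 0.22 to 0.34 in the other 5 clones, and that profile may itself hold part of a gain shared by the clones. Separate gains in each clone stay open, since the start was the same probe in 5 clones but the far end differed in all 6. Sequence missing from part of the reference DNA may account for the gain. Every clone mean was at least 11 times its SE across probes, and the first part of the region was higher than the second in 6 of 6. The sizes differed by up to 0.23, with SEs of at most 0.02. Neighbouring probes share the wave and are not independent, so these SEs are too small. The region was also chosen as a called gain, so its distance from 0 is no evidence. Missing reference sequence and an inherited difference between the mice and the reference both stay open.

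The distal chromosome 14 loss was shared by the 4 thymus clones. An effect of the slide was argued against by #483, which differed from the lower of the spleen clones on its own slide by -0.94. The region was taken from the called loss of #483, so the size of this difference follows in part from that choice and is no independent test. Loss of 1 copy acquired in each leukaemia would be shallower by 0.42 where chromosome 14 had been gained (#003 and #958), if the extra copy kept the sequence. If the extra copy lacked it, the loss would be deeper there. Relative to flanking probes the pairs of clones differed by 0.005 (SE 0.03). This SE is across probes, which are not independent, so it is too small and does not measure the spread between clones. A difference from the reference carried by every copy of chromosome 14 would give equal values and equal ends, and 4 clones had the same first and last probe, which is consistent with an inherited difference between mice as a hypothesis. Strain and relation of the mice are not in the labels, so organ and inheritance could not be separated.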

How the results depend on the processing

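The removal of the shared wave and the joining of segments were chosen after seeing the data, and the cause of the changes below was not tested unless stated. No value recomputed for this part reversed, but region means with the wave removed over 51 probes are not among them. There, 2 of 41 region means of at least 0.25 in either direction changed sign, the chromosome 6 loss of #007 (-0.77 to 0.009) and the chromosome 12 gain of #958 (0.38 to -0.05), since that profile also holds regions shared by several clones. All 98 medians of the gained chromosomes under alternatives stayed within their spread (0.44 to 0.61), as did 995 of 1013 region means. These totals include alternatives that changed only the calls (thresholds, penalties, minimums of probes and joining). Such alternatives leave medians and region means the same by construction. Of the 18 region means that moved, 16 did so under normexp, out of 78 under that setting. The difference between organs in altered percent was 5.73 to 26.8 points over alternatives (exact permutation p = 0.133 to 0.267) and 6.64 to 17.1 leaving out 1 clone (exact permutation p = 0.1 to 0.4). On the slide with both organs alone it was 4.01 points, without a p. Shared sequence was 55.3 to 333 Mb over alternatives and 2.51 to 80.4 Mb leaving out 1 clone, with every permutation p at or under 0.0443. None of the 8 lists passed under any alternative. The chromosome 12 gain was called in 5 clones at a threshold of 0.40 (at most 4 of them at 1 probe), in 5 with the longer wave profile removed and in 2 with the wave removed over 51 probes, which in part is by construction.

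With normexp, #003 had 64 and #1065 5 called segments. At a threshold of 0.15, altered sequence was 27.8% in #003, 51.2% in #007, 29.8% in #958 and 2.77% in #1003, with 189 segments in #003, 116 in #958, 31 in #1003 and 555 in all. At 0.40 #007 had 10.5% and 46 segments, the total was 122 and whole-chromosome gains were 2. With normexp, whole-chromosome gains were 6. With at least 10 probes, #003 had 18 and #1065 5 segments, fewer by construction. With the shared wave removed over 51 probes #007 had 18.8% and 14 segments, with a total of 82, and with the longer profile 68 segments, with a total of 139.

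Bins against the reference were 0 higher and 0 lower in limma with the wave removed over 51 probes (3162 at an unadjusted p under 0.05), in part by construction, since the profile comes from the other clones. They were 777 and 1205 with the longer profile removed, 412 and 533 of 2392 bins of 1 Mb, and 1505 higher with the slide as a block. Leaving out 1 clone gave 1 to 3127 higher and 0 to 3844 lower bins. Between organs limma gave 886 higher and 19 lower bins on the slide with both organs, and 0 to 545 higher leaving out 1 clone (608 unadjusted with all clones). Tests by gene position, the test of receptor loci with each clone left out, and the GC correction were not run. Dim signal limits the depth of the losses, since in #003 87 of 165 probes on chromosome 4 were well above background. No paired analysis was possible because the clone numbers are not shared between the organs.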

Other observations

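Further short losses were shared by pairs of clones. #483 and #958 had both lost chromosome 19 from 37318631 to 37439851 (11 probes, means of -0.63 and -0.48), where the other clones had means of 0.008 to 0.18. Both spleen clones had lost chromosome 13 from 120187679 to 120283183 (12 probes, -0.36 in #1003 and -0.45 in #1065), where the thymus clones had means of -0.08 to 0.04. Relative to flanking probes, #003 (-0.24) and #958 (-0.13) were also below 0 there, and #007 (0.02) and #483 (0.05) were not. Each of these losses had the same first and last probe in both clones, as did the chromosome 5 loss of #483 and #958. Whether they were acquired or inherited was not tested. On chromosome 8, a pair of probes (116308668 to 116316481) had a mean of -3.01 in #958.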
